A study of Mus musculus with 8 samples.

How the data were processed

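Gene expression was measured by array in 8 samples of total RNA from an immortalized mouse brown adipocyte line. The cells had been differentiated for 8 days and were then kept for 18 h with the vehicle DMSO (4 samples) or with 10 µM of the compound Z16078526 (4 samples), per the labels' protocols. Per the same protocols, RNA was extracted with Trizol, its quality was checked on a Bioanalyser and it was labelled with biotin. The labelling note names an Agilent protocol, while the probe identifiers in the value table are Illumina's. No label says whether the 4 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Array positions, scan batches and dates are not given in the sources used here.

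The authors deposited 1 table with an intensity per probe and array, on a linear scale, for 25697 probes. GenomeStudio, Illumina's array software, is named in the submitters' processing notes, and its version and settings are not given in the sources used here. Between 28.28% and 28.44% of the deposited intensities of an array lay below 0, as background subtraction leaves them. All 8 columns had the same upper quartile (307.989) and the same maximum (41175), as between-array quantile normalization leaves them. No detection p-values were used here. Precision is limited by the number of arrays. Per array, 52.64% to 52.78% of the probes lay above an intensity of 16.

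Intensities were set to at least 16 and the log2 was taken, so a value of 4 on the log2 scale means at or below this floor. No further normalization was applied in the main analysis. Probes were named through the probe table given with the series, in which 23978 probes had 1 gene symbol, none had several and 1719 had no symbol. Symbols were brought up to date through the RefSeq gene table of GRCm38.p6, which held 99.93% of the probes' gene identifiers and changed no symbol. The table was used for names only, and no coordinates are given because the files name no genome build. For each of 16593 genes the probe with the highest mean intensity over the 8 arrays, on the linear scale, was used. Of 1429 genes with at least 2 probes above a mean log2 of 7, the log2 differences of the 2 brightest probes correlated with r = 0.656 across genes, which are not independent replicates. Both probes had the same sign in 86.76% of 506 such genes that were called.

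Differences between the groups were tested with limma 3.58.1 (lmFit and eBayes with a trend of variance on intensity, two-sided) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05, and a second count also required a change of over 1.5-fold. Genes at the floor on all arrays (5504 of 16593) were kept. The prior degrees of freedom were 0.574, and 2.63 in a fit without these genes. Where every array of a group lay at the floor, a fold is a lower bound and is written as at least. Such a fold sets the mean log2 of the brighter group against the floor.

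A total of 55 gene lists were tested with camera, limma's competitive test of a list against the other genes, with a preset correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry, which does not compare a list with other genes, were run beside it. The design, the lists, the rule for naming genes and the other settings to try were fixed before the data were examined. By that rule the text names the 12 genes with the largest increase and the 12 with the largest decrease among called genes whose groups did not overlap and whose brighter group lay above the median of all probes, with clone, accession and predicted-gene names left out. It also names a panel of 16 fat cell genes whatever their result, and up to 4 members with the smallest p in the direction of each called list. Other genes were chosen after their values were seen, and are named to spell out small counts or to describe lists in the closing section. Of the panel, Adrb3 was not analysed here. The list entry Asc1 was left out because RefSeq gives it as a synonym of another gene, Trip4.

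Other settings tried were median centring of each array, a second quantile normalization, a floor of 50, a pseudocount of 16, filters on dim probes, fits without the trend, with robust variance or with array weights, the replicate number as a block, a plain test per gene, the mean of a gene's probes, all probes singly, other thresholds, and each array left out in turn. Some settings were added after seeing the data: genes at the floor left out, the mean deviation of 230 probes with uneven signal among the treated arrays as a covariate, the probe with the highest mean log2 in place of mean intensity, and median centring after the floor. The last of these was the first form of the centring. It was replaced by scaling before the floor after its count had been seen, because it gives every gene at the floor a constant difference between groups, and its values are kept in the closing section. It is also 1 of the 23 settings over which ranges of adjusted p are given. Some ends of those ranges come from it, such as 0.00222 for the interferon list and 0.601 for the heat shock list.

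The procedure was tested on simulated data for the comparison of 4 treated with 4 DMSO arrays over 16593 genes, in which 50 genes were changed at each of 4 fold sizes. It recovered 18% of the genes changed 1.25-fold, 46% of those changed 1.5-fold, 54% of those changed 2-fold and 76% of those changed 3-fold, with 3 false calls among 100. A simulated list of 30 genes raised 1.3-fold was called, and of 50 unchanged lists 0 were. The simulated noise was independent between genes, so this result does not cover lists of correlated genes. Far fewer genes were changed in the simulation than the 2516 called below, so recovery may differ in these data. The changed genes and the raised list were drawn only from genes with a mean DMSO intensity more than 2-fold the floor. Recovery was thus not tested for dimmer genes, among them those at the floor on all arrays. The unchanged lists were drawn from all genes, so they differ from the raised list in brightness as well.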

Results

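Total RNA from 8 samples of differentiated immortalized brown adipocytes was profiled by array, 4 after 18 h with DMSO and 4 after 18 h with 10 µM Z16078526. The stated purpose was to characterize the effect of the compound on these cells, and the single comparison the design holds is treated against DMSO. Values are log2 intensities, in which 4 is the floor. Each array had 13528 to 13564 of 25697 probes above the floor. Log2 values of pairs of arrays correlated across genes with r of 0.9959 to 0.9966 within DMSO, 0.9929 to 0.9952 within treated and 0.9888 to 0.9925 between the groups. The median SD between arrays of a group was 0.115 in DMSO and 0.148 in treated samples, over genes above the floor on all 8 arrays.

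Treated cells had more signal for genes of respiratory chain complex I, PPAR targets, cholesterol synthesis and the proteasome, and less for genes of the extracellular matrix. Lists of fatty acid oxidation, peroxisomes, lipid droplets and the other respiratory complexes were called higher too, but not with an estimated correlation. Some of these lists share members with the PPAR list, so their calls are not separate results. Among the 12 largest increases were Cycs, which encodes cytochrome c, at 3.55-fold (log2 difference 1.83 ± 0.20 SE, adjusted p = 0.00203, n = 4 arrays per group here and below), and Fgf21, which encodes a secreted metabolic hormone, at 3.36-fold (1.75 ± 0.11, adjusted p = 0.000449). The largest decrease was in Lep, the gene for leptin, which was 5.33-fold lower (log2 difference -2.42 ± 0.08, adjusted p = 8.15e-05). Its mean intensity was 1323 in DMSO and 249.0 in treated cells. In all, 2516 of 16593 genes passed an adjusted p of 0.05 in limma, 1323 higher and 1193 lower in treated cells. Of these, 884 changed over 1.5-fold, 469 up and 415 down. The groups did not overlap in 3281 genes (19.77% of those tested), where chance gives 2.857%.

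The other genes with the largest increases were Fabp4 (3.16-fold), the fatty acid binding protein of adipocytes, the G protein subunit gene Gng5 (2.91-fold), the sialyltransferase gene St3gal6 (2.84-fold), Lrrc39 (3.08-fold), Oit3 (3.05-fold), Sarnp (2.96-fold), Ier2, Lin7c, Bmt2 and Krt23. Fabp4 was read by 1 probe at low signal, with a mean intensity of 93.7 in DMSO and 295 in treated cells, against 22846 for Adipoq in DMSO. Krt23, a keratin gene, lay at the floor on all 4 DMSO arrays and was at least 3.08-fold higher in treated cells. The immediate early gene Ier2 was above the floor on only 1 DMSO array, and Lin7c and Bmt2 on 2 each, so their log2 differences of 2.08, 1.90 and 1.70 are measured largely against the floor. The other large decreases were in Eln, the gene for elastin (4.19-fold lower), Lgi4 (4.06-fold), Spon2 (4.03-fold), the chloride channel gene Ano1 (3.81-fold), Tnfrsf11b, which encodes osteoprotegerin (3.72-fold), the procollagen processing gene Pcolce2 (3.65-fold), the kinase gene Camk2b (3.54-fold), Abi3 (3.30-fold), the transcription factor gene Sox9 (3.24-fold) and the periplakin gene Ppl (3.16-fold). Sox18, a transcription factor gene of endothelium, lay at the floor on all 4 treated arrays and was at least 3.42-fold lower. Lgi4 and Ano1 were each above the floor on 3 treated arrays. With a covariate for uneven signal among the treated arrays, described with the array values, 6 of these genes lost their calls (adjusted p 0.0532 to 0.118). The log2 differences of Ano1 (-2.04 ± 0.45), Ppl (-1.52 ± 0.40) and Bmt2 (1.56 ± 0.46) stayed within 1 SE of their first values while their SE grew, and those of Lgi4 (-1.30 ± 0.33), Lin7c (1.44 ± 0.35) and Krt23 were smaller. Other probes of similar brightness gave smaller changes for Lrrc39 (0.50) and Pcolce2 (-0.97), and with the probe of highest mean log2 Lrrc39 was not called (adjusted p = 0.0686) while Pcolce2 was (0.0178). With the replicate number as a block, Lin7c (adjusted p = 0.0876), Bmt2 (0.105), Krt23 (0.0627), Lrrc39 (0.0921), Lgi4 (0.0676) and Tnfrsf11b (0.065) lost their calls.

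Of the panel of brown fat genes, Cidea, which encodes a lipid droplet protein of brown fat, rose 2.23-fold (log2 1.16 ± 0.06, adjusted p = 0.000416). Pdk4, a kinase that restrains pyruvate oxidation, rose 1.70-fold (adjusted p = 0.00218). Ucp1, the uncoupling protein of brown fat, rose 2.59-fold (1.37 ± 0.23, adjusted p = 0.0103) at low signal, from a mean intensity of 30.2 in DMSO to 76.7. Cox8b rose 1.47-fold (adjusted p = 0.0405), and Pparg, the receptor that drives fat cell differentiation, was 1.35-fold lower (log2 -0.44 ± 0.05, adjusted p = 0.00309). Log2 differences that did not pass were 0.24 for Ppargc1a (adjusted p = 0.229), 0.65 for Cpt1b (0.0859), 0.22 for Plin1 (0.0959), -0.23 for Pnpla2 (0.0564), 0.08 for Lipe (0.997) and -0.04 for Adipoq (0.893), the adiponectin gene and at a log2 level of 14.48 in DMSO. Dio2 and Prdm16 lay at the floor on all 8 arrays, and Elovl3 was above it on 2 treated arrays only, with a log2 difference of 0.18 (adjusted p = 0.428) that became 1.27 and was called with a pseudocount of 16 (0.0135). With the covariate for uneven signal, Ucp1 lost its call (adjusted p = 0.0562) through a larger SE, at a log2 difference of 1.49 ± 0.34, and Cox8b (0.316) with a smaller difference as well, 0.34 ± 0.16. These were the largest adjusted p over 23 other settings, in which the smallest were 0.000174 and 0.000462. The replicate number as a block ended the calls of Ucp1 (adjusted p = 0.0533) and Cox8b (0.140), and a floor of 50 that of Cox8b (0.054). Cox8b also lost its call when any array but treated 1 was left out (adjusted p 0.0563 to 0.110), Plin1 gained one without treated 4 (0.0339) and Pnpla2 without DMSO 3 (0.0359). Cpt1b, Plin1 and Pnpla2 were also called under several settings with all arrays in, among them both filters on dim probes, with smallest adjusted p of 0.00601, 0.0233 and 0.00487.

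**Figure D1:**
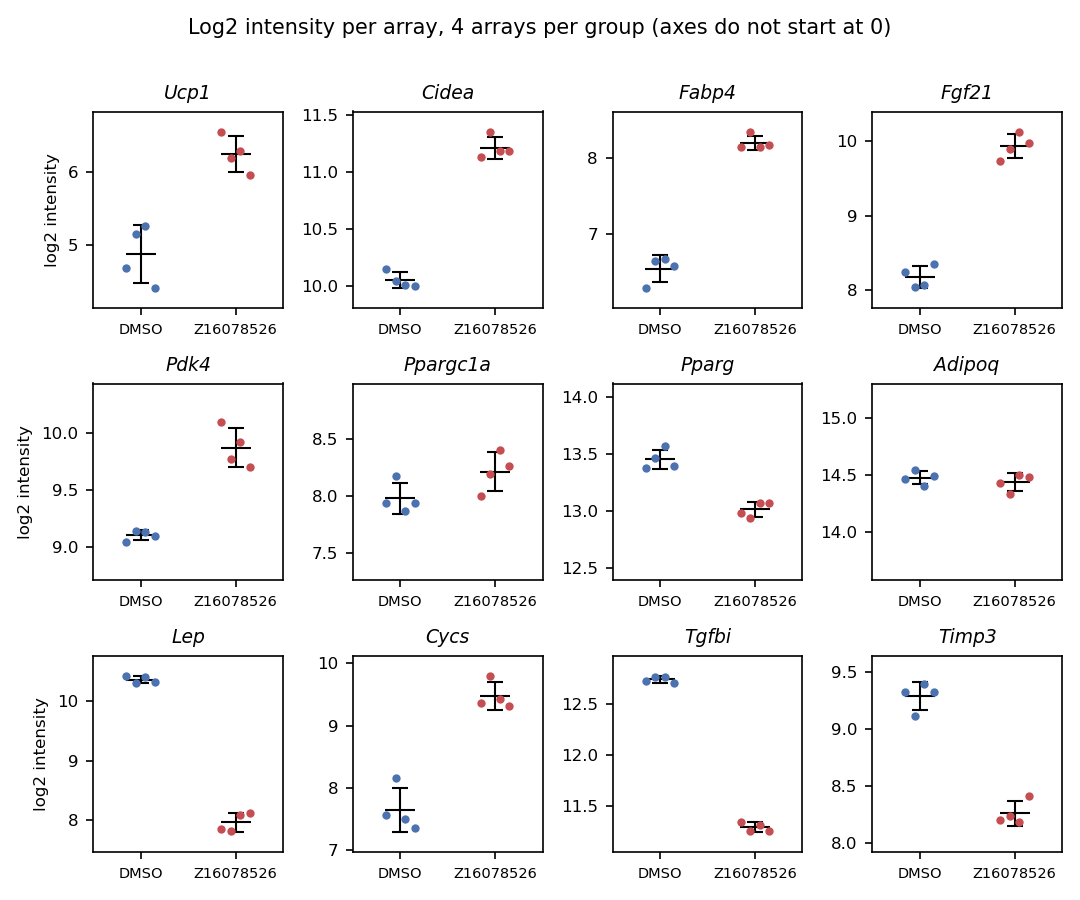
Log2 intensity of 12 genes on each of the 8 arrays, with DMSO on the left and Z16078526 on the right of each panel. Points are arrays, bars are the mean and SD of 4 arrays, and the vertical axes differ between panels. Cidea, Fabp4 and Fgf21 lie higher and Lep and Tgfbi lower on all treated arrays, while Adipoq differs by -0.04.

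The list of thermogenic and brown fat identity genes as a whole was not called by camera (adjusted p = 0.187, and 0.0368 to 0.643 over 23 other settings, of which only the pseudocount of 16 gave a call). By fry, which does not compare a list with other genes, this list had an adjusted p of 0.0116. Of its 38 measured members 6 were higher (Fgf21, Ucp1, Cidea, Nrg4, Pdk4 and Cox8b) and 3 lower (Gamt, Slc6a8 and Alpl), with the same counts adjusted over the list alone. The adipogenesis and mature adipocyte list was not called either (adjusted p = 0.786), with 9 of 36 higher and 8 lower (10 and 11 adjusted over the list alone). Its members went both ways: Fabp4, Plin2, Plin5, Cidec and Fabp5 rose, and Lep, Orm1, Gpam, Sncg and Srebf1 fell. Its median log2 difference (0.04) and its mean (-0.04) differed in sign. Of 16 white fat markers, Psat1 rose and Lep, Fst and Ccdc3 fell (1 and 3 adjusted over the list alone, list adjusted p = 0.576, and 0.000137 by fry).

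Target genes of the PPAR receptors rose together (adjusted p = 1.31e-07, and 0.0235 with an estimated correlation). Of 45 measured, 18 rose and 2 fell, Fndc3b and Plin4 (23 and 2 adjusted over the list alone). Apart from Cidea, Fabp4 and Fgf21, the members with the smallest p included Angptl4, an inhibitor of lipoprotein lipase (1.60-fold, adjusted p = 0.000449). The lipolysis and lipid droplet list was called higher (adjusted p = 0.00939, but 0.263 with an estimated correlation), with 8 of 19 up and 2 down, Mgll and Plin4 (9 and 3 adjusted over the list alone). The droplet genes Hilpda (1.93-fold) and Plin5 (1.88-fold) and the glycerol channel gene Aqp7 (1.71-fold) rose, while the lipase genes Pnpla2 and Lipe did not pass. A floor of 50 ended this list's call (adjusted p = 0.0606, and 0.00256 to 0.454 over 23 settings). Of 22 genes of mitochondrial fatty acid oxidation, 7 rose and 0 fell (8 and 0 adjusted over the list alone, list adjusted p = 0.00159, and 0.0808 with an estimated correlation), among them Hadhb (1.56-fold), Acadvl (1.36-fold), Cpt2 (1.33-fold) and the carnitine transporter gene Slc22a5 (1.32-fold). With the mean of a gene's probes, Slc22a5 (log2 difference 0.14, adjusted p = 0.412) and Aqp7 (0.44, 0.0617) were not called. Of 28 peroxisome genes, 8 rose and 0 fell (12 and 2 adjusted over the list alone, list adjusted p = 0.00162, and 0.0797 with an estimated correlation), with the smallest p for the thiolase gene Acaa1b (1.95-fold), Pex16 (1.57-fold), Ech1 and Pex2 (each 0.32 on the log2 scale). Pex2 turned sign with the mean of a gene's probes (log2 difference -0.01) and lost its call with the covariate for uneven signal (0.35 ± 0.08, adjusted p = 0.0637). These lists overlap with that of the PPAR targets, to which Cidea, Hilpda, Plin5, Aqp7, Hadhb, Acadvl, Cpt2 and Ech1 also belong.

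Nuclear genes of respiratory chain complex I rose with the smallest p of the 55 lists (adjusted p = 6.49e-12, and 0.0235 with an estimated correlation). Of 34 measured, 20 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 difference of 0.20. At an unadjusted p under 0.05, 25 were higher and 0 lower, and a plain test per gene called 19 higher and 0 lower. Ndufb2 rose 1.95-fold and Ndufb10 1.47-fold, while Ndufb3 and Ndufs8, at log2 levels above 13, each rose 1.16-fold. The list of complexes II to IV with cytochrome c had 8 of 28 up and 0 down (11 and 0 adjusted over the list alone, list adjusted p = 0.00124, and 0.0841 with an estimated correlation), with Cox7b at 2.60-fold, Sdhd at 2.07-fold and Cox6a2 at 1.72-fold beside Cycs. Of 27 TCA cycle and pyruvate dehydrogenase genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone, list adjusted p = 4.37e-05, and 0.0613 with an estimated correlation), among them Dlat (1.63-fold) and Pdha1 (1.33-fold). Of 76 mitochondrial ribosome genes, 22 rose and 4 fell, Mrps26, Mrpl10, Mrps12 and Mrpl17 (24 and 5 adjusted over the list alone, list adjusted p = 5.78e-06, and 0.0841 with an estimated correlation). Mrps28 (1.57-fold), Mrpl24 (1.37-fold), Mrpl27 (1.35-fold) and Mrpl1 (log2 difference 0.38) had the smallest p of this list's risers, and larger rises were called in others, such as Mrpl39 (0.86) and Mrps10 (0.77). The ATP synthase list was not called (adjusted p = 0.146), with 3 of 17 up (Atp5a1, Atp5e and Atp5h) and Atpif1 down (4 and 1 adjusted over the list alone), but it was called without treated 3 (0.0482) and with the covariate for uneven signal (0.0157), in a range of 0.0157 to 0.974 over 23 settings.

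**Figure D2:**
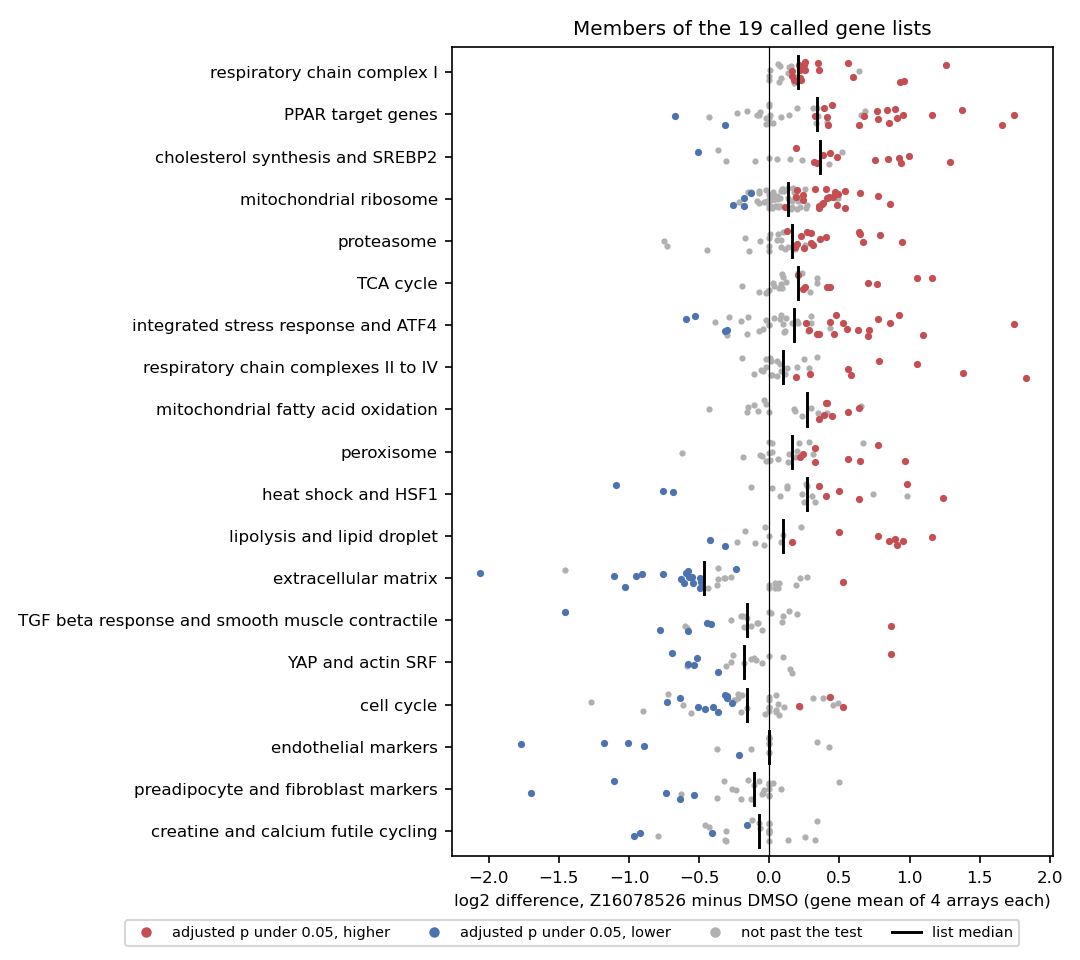
Log2 difference of each member of the 19 called lists, treated minus DMSO, with 1 point per gene and a bar at the list median. Red and blue points passed an adjusted p of 0.05 and grey points did not. The complex I median lies at 0.20 and the extracellular matrix median at -0.46.

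Enzymes of cholesterol synthesis and other SREBP2 targets rose (adjusted p = 5.73e-06, and 0.0283 with an estimated correlation). Of 22 measured, 12 rose and 1 fell, Lpin1 (15 and 2 adjusted over the list alone). Tmem97 rose 2.00-fold, the decarboxylase gene Mvd 1.91-fold, the lanosterol synthase gene Lss 1.90-fold, and Msmo1 by 0.48 on the log2 scale. The list for fatty acid and triglyceride synthesis was not called (adjusted p = 0.327, and 0.013 to 0.643 over 23 settings), with 3 of 30 up (Acsl3, Dgat1 and Acss2) and 7 down (4 and 8 adjusted over the list alone). It was called lower at a floor of 50 (0.0214) and with centring after the floor (0.013).

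Proteasome subunit genes rose (adjusted p = 1.51e-05, and 0.0452 with an estimated correlation), 17 of 36 up and 0 down (18 and 2 adjusted over the list alone). Psmb5 rose 1.72-fold, and Psmb3, Psmc2 and Psmd10 between 1.19-fold and 1.23-fold. Psmd10 was not called with the mean of a gene's probes (log2 difference 0.08, adjusted p = 0.712), nor Psmc2 with the covariate for uneven signal (0.22 ± 0.05, adjusted p = 0.0614). The list of the integrated stress response and its factor ATF4 was called higher (adjusted p = 0.000521, but 0.0841 with an estimated correlation), with 17 of 46 up and 4 down, Slc7a5, Atf5, Slc6a9 and Slc1a4 (20 and 5 adjusted over the list alone). The tRNA synthetase genes Lars and Nars rose 1.89-fold and 1.71-fold, and Ppp1r15a, which encodes a regulator of the phosphatase that acts on eIF2, 1.55-fold. Fgf21 (3.36-fold) is also among the 4 risers of this list named by the rule, so its rise does not belong to the PPAR list alone. Of 22 heat shock genes, 6 rose and 3 fell (9 and 3 adjusted over the list alone, list adjusted p = 0.00764, and 0.421 with an estimated correlation). The risers named by the rule were the chaperonin genes Cct4 (1.56-fold) and Hspd1 (1.32-fold) and the cochaperone genes Chordc1 (1.41-fold) and Stip1 (1.28-fold). Those that fell were Cryab, Hspa1a and Bag3, a small heat shock protein, an inducible chaperone and a cochaperone. A second, dimmer probe of Hspd1 gave a log2 difference of -0.64. It is one of the probes with uneven signal, with a difference of -1.97 between treated 3 and treated 1, where the tested probe differed by 0.02. The heat shock call was lost with a floor of 50 (adjusted p = 0.147), the mean of a gene's probes (0.0857) and the covariate for uneven signal (0.0658, with a median log2 difference of 0.15 against 0.27 without it), in a range of 0.000626 to 0.601 over 23 settings. The list of the unfolded protein response of the endoplasmic reticulum was not called (adjusted p = 0.303, and 0.0279 to 0.643 over 23 settings, with a call at a floor of 50), with 6 of 29 up and 6 down (6 and 9 adjusted over the list alone).

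Extracellular matrix genes fell (adjusted p = 7.26e-10, and 0.0235 with an estimated correlation). Of 36 measured, 18 fell and 1 rose, P4ha1 (23 and 1 adjusted over the list alone), with a median log2 difference of -0.46. Eln is a member, and those with the smallest p were Timp3, an inhibitor of matrix proteases (2.04-fold lower), the laminin gene Lamc1 (1.93-fold), Sparc (1.52-fold) and Col5a1 (1.49-fold). The list of TGF beta response and smooth muscle contractile genes was called lower (adjusted p = 0.00199, but 0.158 with an estimated correlation), with 5 of 23 down and Ccn1 up (8 and 2 adjusted over the list alone). Tgfbi fell 2.74-fold (adjusted p = 8.75e-06), Acta2 1.49-fold and Itgb5 1.36-fold. Actg2 was dim, lay at the floor on all treated arrays and was at least 1.72-fold lower, and its call ended at a floor of 50 (adjusted p = 0.391) and with robust variance (0.0615). Tgfb1 had a log2 difference of -0.42. The list of YAP and actin-regulated SRF targets was called lower (adjusted p = 0.00225, but 0.171 with an estimated correlation), with Axl (1.62-fold), Acta2, Myh9 (1.45-fold), Zyx (1.43-fold) and Actb down and Ccn1 up among 19 members (7 down and 1 up adjusted over the list alone).

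Markers of preadipocytes and fibroblasts were called lower (adjusted p = 0.00939, but 0.119 with an estimated correlation), with 5 of 27 down, Sox9, Dcn, Klf2, Vim and Cd9, and 0 up (5 and 0 adjusted over the list alone). Dcn, the gene for the matrix protein decorin, fell 2.15-fold, Klf2 1.66-fold and Cd9 1.45-fold. Endothelial markers were called lower (adjusted p = 0.00933, but 0.0841 with an estimated correlation), with 5 of 16 down and 0 up (6 and 1 adjusted over the list alone). Only 9 of these 16 genes were above the floor on any array, so the list's median was 0 while its mean was -0.30. Plvap fell 2.26-fold and Ramp2 2.01-fold, Flt1 had a log2 difference of -0.90, and Tek, barely above the floor in DMSO, was at least 1.16-fold lower. The call of the fibroblast list was lost with the covariate for uneven signal (adjusted p = 0.0913, the largest of 23 settings, with 0.00191 the smallest), with a median of -0.11 both with and without the covariate, and that of the endothelial list with a floor of 50 (0.0520, in a range of 0.00372 to 0.121). Klf2 lost its call without DMSO 1, 2 or 3 or treated 3 (adjusted p 0.0590 to 0.0727), and Cd9 without any DMSO array or treated 2 (0.0520 to 0.0868).

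Cell cycle genes were called lower (adjusted p = 0.00764, but 0.0841 with an estimated correlation), with 10 of 43 down and 3 up, Aurka, Rrm1 and Mcm2 (15 and 5 adjusted over the list alone). Cdt1, a licensing factor of replication, fell 1.55-fold, the mitotic kinase gene Plk1 1.42-fold, the centromere gene Cenpa 1.29-fold and Cdc20 1.24-fold. Genes of creatine and calcium cycling were called lower (adjusted p = 0.0175, but 0.187 with an estimated correlation), with 4 of 24 down and 0 up (5 and 0 adjusted over the list alone). All 4 belong to creatine handling or are linked to it: the creatine kinase gene Ckb (1.95-fold), Gamt (1.90-fold), the transporter gene Slc6a8 (1.33-fold) and Alpl (1.12-fold). Gamt, Slc6a8 and Alpl are the same genes that fell in the thermogenic list, so the 2 results are not independent. Alpl, at an adjusted p of 0.0456, lost its call without DMSO 1, 2, 3 or 4 or treated 2, 3 or 4 (up to 0.114). It also lost its call with all arrays in, with robust variance (0.343), a pseudocount of 16 (0.164), both filters on dim probes, a floor of 50 and median centring. Fits without the trend, with genes at the floor left out, with the replicate number as a block (0.125) and with the covariate for uneven signal (0.284) ended it too. The list's call ended with that covariate (0.0658, the largest of 23 settings, with 0.0072 the smallest), at a median of -0.04 against -0.07 without it.

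Of 53 cytosolic ribosome genes, Rpl4 rose and Rps9 and Rps15 fell (0 and 1 adjusted over the list alone, list adjusted p = 0.693). Of 20 glycolysis genes, 0 passed the limma test in either direction, over all genes or adjusted over the list alone (list adjusted p = 0.923), a plain test per gene gave 0, and at an unadjusted p under 0.05 3 were higher and 1 lower. Macrophage markers had 0 calls of 18 and lymphocyte and mast cell markers 0 of 13, with only 6 and 5 of them above the floor on any array (list adjusted p = 0.888 and 0.746). A plain test called 0 of either, and at an unadjusted p under 0.05 the counts were 0 and 1. Of 13 nerve and Schwann cell markers Mbp fell (list adjusted p = 0.888). Of 23 skeletal muscle markers Tnnc1 rose and Mb, Myl1 and Des fell (list adjusted p = 0.327). The type I interferon list missed the threshold (adjusted p = 0.0542, and 0.726 with an estimated correlation, which was 0.465), with 1 of 36 up, Isg20, and 1 down, Gbp2 (1 and 0 adjusted over the list alone). Fry gave it an adjusted p of 0.506. Of the 35 ways to split the 8 arrays into 4 and 4, 26 gave a camera p as small, the real one included. With the preset correlation the interferon list was called lower without DMSO 1 (0.0312), DMSO 2 (0.0231), DMSO 4 (0.00436) or treated 1 (0.00827), and with all arrays in under median centring (0.0487), a floor of 50 (0.0111), a pseudocount of 16 (0.00971), array weights (0.0294) and the mean of a gene's probes (0.0375), in a range of 0.00222 to 0.946 over 23 settings. Other lists that were not called included hypoxia (8 of 28 up and 2 down, adjusted p = 0.0948), LXR targets (2 of 16 up and 4 down, 0.146), the mitochondrial unfolded protein response (3 of 14 up and 1 down, 0.193), NF-kB and inflammation (2 of 31 up and 2 down, 0.509), housekeeping genes (1 of 14 up and 4 down, 0.576) and p53 targets (3 of 25 up and 4 down, 0.962). In the same order, fry gave these lists an adjusted p of 0.0037, 0.000488, 0.0173, 0.214, 0.00356 and 0.797. In all, 19 of the 55 lists were called, 12 higher and 7 lower, and 5 of them also with an estimated correlation. Those 5 were complex I, extracellular matrix, PPAR targets, cholesterol synthesis and proteasome. Several of the other called lists had as small a p in other splits of the arrays, as given in the closing section.

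The 4 treated arrays were not alike at a set of 217 probes, which were chosen as bright, even among DMSO arrays and at least 1 log2 unit brighter on treated 1 than on treated 3. Their mean deviation from the DMSO mean was -0.02 on treated 1, -0.63 on treated 2 and -1.40 on treated 3, and also -0.63 on treated 4. Only 6 probes met the same rule with treated 1 and 3 exchanged. The probes tested for 10 called genes were among the 217. Bright here means a DMSO mean above a log2 of 7, so dimmer genes with uneven signal are not in this count. Lgi4, at a DMSO mean of 6.60, differed by -1.58 between treated 3 and treated 1. Several list shifts were present on treated 1 as well: the complex I median lay 0.22 above DMSO on treated 1 and 0.19 on treated 3, the PPAR target median 0.28 and 0.39, and the extracellular matrix median -0.43 and -0.51. The median of cell cycle genes was -0.15 on treated 1 and -0.02 on treated 3, and that of TGF beta and smooth muscle genes -0.19 and -0.05. The median of creatine and calcium cycling genes was 0 on treated 1, against -0.15, -0.08 and -0.21 on treated 2, 3 and 4. With the mean deviation of 230 such probes, 13 of them without a gene name, as a covariate, 1482 genes were called, 627 higher and 855 lower, of which 1251 were among the 2516. This covariate lay near 0 on the DMSO arrays and at -0.62, -1.39 and -0.62 on treated 2, 3 and 4. It is thus partly tied to group, which can widen the SE, so a call lost with it does not by itself show an artefact.

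**Figure D3:**
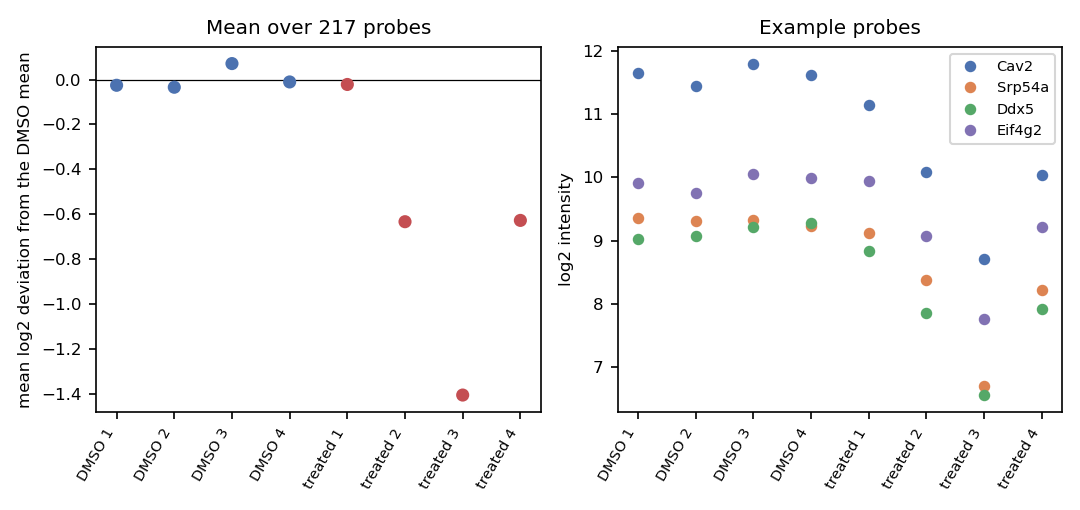
Left, mean log2 deviation from the DMSO mean of the 217 probes with uneven signal on each of the 8 arrays, with DMSO in blue and treated in red. Right, log2 intensity of 4 such probes on each array, in which treated 3 lies lowest for Cav2, Srp54a, Ddx5 and Eif4g2. The probes were chosen by the difference between treated 1 and treated 3, so only treated 2 and 4 were free of that choice.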

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

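Of the tests in this part, those of the uneven probes, of complex I against them, of fibroblast-like cells, of the bright-probe ratio with a covariate and of splits with an estimated correlation were chosen after the results they concern had been seen. The test of uneven response was replaced as the main one after its value was known, and both values are given.

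The first pattern is the set of 217 probes of 185 genes with uneven signal among the treated arrays. Among 125 of these genes with another probe above a log2 of 7, the brightest such probe changed from treated 1 to treated 3 by a median of -0.0281 of the uneven probe's change (95% bootstrap interval -0.061 to 0.0307). A change of the whole transcript needs a value near 1, or a smaller positive one where the signal of a bright probe is compressed. A first form of this test, with other uneven probes left out, gave -0.0614 over 130 pairs. In 18.4% of the genes (95% interval 12 to 26.3) the other probe fell by at least 0.5 of that change, a share that compression of bright probes may make too small. The shift of members of the 5 lists called with an estimated correlation was 1.21 times as large on treated 3 as on treated 1 (0.871 to 1.43). Both values argue against an unequal response of the samples as the whole source. Loss of signal at single probes is consistent with these values, while changes in the transcript form a probe reads were not tested and stay open, and the labels name no batch.

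The second pattern is the opposite shift of complex I and extracellular matrix genes. If the uneven probes were the source, both shifts should be near 0 on treated 1, but treated 1 held 1.2 times the complex I shift of treated 3 (95% bootstrap interval 0.797 to 1.53) and 0.844 times the matrix shift (0.536 to 1.4). Both lists also kept their calls with the mean deviation of the uneven probes as a covariate. Fewer fibroblast-like cells in the treated wells would lower their markers alike only if no other cells made them, which was not measured. Of 16 markers above the floor, 4 had 95% intervals entirely above those of at least 2 others, with Itgb1 at 0.49 and Sox9 at -1.70. All but Itgb1 and Twist1 (0.08) had negative differences. The falls were thus unequal, but this cannot decide whether the share of such cells was smaller. An effect of the compound may underlie both shifts, as a hypothesis, since array position and culture are not given in the sources used here.

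A further pattern is that complex I genes with bright probes differed less than those with dimmer probes, a median of 0.18 over 22 genes above a log2 of 13 against 0.93 over 5 genes between 8 and 12. Over 51 genes with a probe in each range, the spread of log2 differences of the bright probe was 0.45 of that of the dimmer probe (95% bootstrap interval 0.323 to 0.591), which is consistent with compression of bright signals. With the uneven-probe covariate the ratio was 0.528 (0.404 to 0.725) and on treated 1 alone 0.528 (0.403 to 0.745), so the uneven probes do not account for all of it. Fold changes of the brightest genes may therefore be too small, and a true difference between subunits stays open.

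In 9 of 197 tests of a named gene in a group, 1 array lay far from the other 3, where chance alone gives about 1 in 20. The gap to the nearest array as a share of the group's range was 1 for Ier2 in DMSO (array 2, the only one above the floor), 0.977 for Bmt2 in DMSO (array 2), 0.844 for Psmb3 in DMSO (array 4), 0.849 for Fabp4 in treated cells (array 2), 0.904 for Cox8b (treated 1), 0.86 for Sparc (treated 1), 0.881 for Lamc1 (treated 1), 0.879 for Pex16 (treated 2) and 0.898 for Hspd1 (treated 4). Outside the named genes, 192 of the 1719 probes with no gene name passed an adjusted p of 0.05, 96 higher and 96 lower.

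Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many genes (2516 against at most 2 in the others) and 1 as many genes over 1.5-fold (884 against at most 2). Chance is thus an unlikely source of both counts, but 1 of 35 is the smallest share this test can give. The splits cannot tell treatment from an array position or batch shared by a group. For the number of lists, 2 of the 35 gave as many (19 against 24 in the highest other), so chance cannot be excluded for that count with a preset correlation. The split with 24 lists differed from the real one by the exchange of DMSO 1 and treated 4, and the 16 splits with 1 such exchange gave 6 to 24 lists while the 18 with 2 gave 0 to 4. Counting the real split, as small a camera p arose in 8 splits for heat shock and 7 for creatine and calcium cycling. It arose in 5 each for mitochondrial ribosome, YAP and fibroblast genes, and 4 for TGF beta. Cell cycle and lipid droplet lists had 3 each, and peroxisome, complexes II to IV, TCA cycle and stress response lists 2 each. For the other called lists only the real split did. With an estimated correlation, 1 of the 35 gave as many lists (5 against 0 in the highest other), again the smallest share possible.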

How the results depend on the processing

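The counts stayed within 1.5 times of 2516 genes, 884 genes over 1.5-fold and 19 lists under centring before the floor, a second normalization, floor, pseudocount, filters, trend, robust and weighted fits, the plain test, the mean of probes and all probes singly. Leaving out each array gave 1774 to 2465 genes, 700 to 936 genes over 1.5-fold and 19 to 20 lists. An adjusted p of 0.01 gave 1194 genes and a 2-fold minimum 189, as stricter thresholds must. Camera with an estimated correlation called 5 lists, and fry, which does not compare with other genes, called 37. All 19 lists were among the 37. So were lists that camera did not call, such as NRF2 (fry adjusted p = 0.0037), receptors of fat cells (0.00672) and cAMP (0.0116). The lists of the endoplasmic reticulum response (0.0125) and the circadian clock (0.0248) were others. Chosen after seeing the data were 4 settings. With the probe of highest mean log2, 2514 genes were called, 2513 of them among the 2516. Without genes at the floor 3298 genes were called. With the uneven-probe covariate 1482 were called (627 higher, 855 lower), over 1.5-fold 652, and 17 lists, with 1 term more in the model. Centring after the floor gave 9192 (7554 higher, 1638 lower) by construction, since all 5504 genes at the floor were called, and only 13 lists, of which 9 were among the 19; the proteasome, TCA cycle and mitochondrial ribosome lists were among those lost. Of named genes, Hspd1 and Pex2 turned sign with the mean of a gene's probes (-0.116 and -0.0148, neither called), because dimmer probes with negative differences enter the mean; that of Hspd1 is one of the uneven probes. Signal over background limits genes near the floor: Tek, Actg2, Krt23, Sox18, Lin7c and Bmt2 lost their calls at a floor of 50. The brighter genes Cox8b and Alpl lost theirs at that floor too, at adjusted p of 0.054 and 0.0591. With the uneven-probe covariate Pex2, Tek, Klf2 and Alpl lost theirs with SE at least 1.44 times as large, and Cd9 with a smaller difference (-0.29 against -0.54).

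The samples share only replicate numbers: same-numbered arrays' deviations from their group means correlated at -0.0745, 0.0667, -0.198 and 0.186. The fit with the replicate number as a block called 1123 genes, 465 over 1.5-fold and 19 lists, with fewer residual degrees of freedom. Of the named genes, 18 lost their calls in it, at adjusted p of 0.0501 to 0.140. They were Ucp1, Cox8b, Lin7c, Bmt2, Krt23, Lrrc39, Lgi4, Tnfrsf11b, Ndufs8, Pex2, Dcn, Klf2, Cd9, Itgb5, Tek, Cdc20, Cenpa and Alpl.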

Other observations

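The tests of the mitochondrial import, ribosome biogenesis and acute-phase lists were written after the results that prompted them had been seen, and before their own values were; their members and the genes named in this part were chosen after the main results.

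Of the lists outside the called ones, those for NRF2, cAMP and the circadian clock held members that went opposite ways. Of 32 genes of the NRF2 and glutathione list, 9 rose, among them Txn1 (log2 difference 0.93), Cbr3 (0.86) and Hmox1 (0.70), and 5 fell, Gstm1 (-0.82), Gstp1, Tkt, Gclm and Gstm2 (list adjusted p = 0.332). Of 25 genes of the cAMP and CREB list, 6 rose, Ier2, Atf3 (1.09), Fos (1.02), Crem (0.97), Pde4d (0.77) and Ier3, and 3 fell, Cited2 (-1.02), Gadd45b (-1.02) and Rgs2 (list adjusted p = 0.366). Of 22 receptor genes of fat cells, 4 rose, the receptor genes Hcar2 (1.20), Tshr (0.92), Npr3 (0.85) and Ffar2 (0.42), and 0 fell (list adjusted p = 0.327). In the circadian clock list of 18, 5 rose, Nr1d2 (0.95), Nr1d1 (0.62), Rora, Clock and Ciart, and Nfil3 fell (list adjusted p = 0.913). The endoplasmic reticulum chaperone genes Hspa5 (1.03) and Pdia6 (0.83) rose while Edem1 (-1.12) and Edem2 (-0.59), of the degradation pathway, fell.

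A first hypothesis was that genes of mitochondrial protein import rose with those of respiration and mitochondrial translation. Of 34 measured, 11 rose and 0 fell, and camera gave p = 2.73e-07 with the preset correlation and p = 0.00411 with an estimated one, which is consistent with it. The list's median log2 difference was 0.28, and the risers included Timm10, Timm9, Tomm22 and Grpel1.

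A second hypothesis was that ribosome biogenesis genes rose, after Rrp8 and Tsr1 were seen among the genes with higher values. Of the 56 other members measured, 14 rose and 3 fell (camera p = 0.000127, and 0.0356 with an estimated correlation), with a median of 0.13, which may point to a small shift of the group.

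Another hypothesis, that acute-phase and complement genes fell as a group, came from the low values of Hp, Orm1, Lbp, C4b and Itih4. Of the 38 other members, 3 fell, Orm2, Serpina3n and Socs3, and 0 rose, and camera gave p = 0.406 (0.368 with an estimated correlation), so the other members gave no evidence for it.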
